A study of Ambystoma mexicanum and Ambystoma andersoni and Ambystoma maculatum with 18 samples.

How the data were processed

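RNA was measured in the distal tip of the forelimb of larvae of 3 salamander species, Ambystoma mexicanum (the axolotl), A. andersoni and A. maculatum (the spotted salamander). Limbs were cut through the middle of the zeugopod, the lower arm. The most distal 1 mm of tissue was taken at amputation (0 h) or 24 h later. Each library pooled tissue of 5 larvae, and each of the 6 groups (3 species at 2 times) had 3 libraries, 18 in all. The libraries of a group are treated as separate pools of animals, which the pool size alone does not show. Per the labels, libraries were made with an Illumina TruSeq RNA kit. The depth aimed at was about 50000000 read pairs of 100 bp each per library.

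The deposited values are expected counts per assembled feature, which the authors made with RSEM per the labels and the submitters' processing notes. An expected count is an estimate that divides reads matching several features among them, so near-identical features can trade counts and each is uncertain to that extent. The RSEM version, the aligner, the assembler and the source of the assemblies are not given in the sources used here. There are 3 tables, 1 per species, and 0 columns of values were left unused. The feature IDs carry a species prefix, a component number and a feature number within the component, and no gene name. The table of RefSeq genes used for names (assembly UKY_AmexF1_1) was searched, and 0 IDs of each species' table were found in it, so no feature was matched to a gene and features appear under their own IDs. The same number in the tables of different species does not mark the same gene. Among IDs with a mean log2(CPM + 1) of at least 1 in both tables, Pearson's r of these means across features was -0.055 for A. mexicanum and A. andersoni (271 IDs), -0.111 for A. mexicanum and A. maculatum (204 IDs) and -0.004 for A. andersoni and A. maculatum (1023 IDs).

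The tests per feature and per gene and the rule for named features were fixed before the data were examined. So were the first set of alternatives and 22 gene lists. Measures of whole libraries and their permutation tests, within and between species, were not in that plan. The planned tests per gene symbol, the gene lists, the overlap of calls among species, the species-by-time test per gene and the correlation of fold changes between species all need gene names and were not made. Levels and fold changes of single features were compared only within a species, except the share of counts in the most abundant feature of each table, a measure of the whole library, whose change was compared between species although the features are not matched to each other.

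Expected counts were rounded to whole numbers. For each species, the 3 libraries at 24 h were compared with the 3 at 0 h by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and time as the only term. Features were kept by filterByExpr with its defaults, a minimum count of 10 scaled to library size and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method over the tested features of a species, and the threshold was an adjusted p of 0.05. The plan named no version of the quasi-likelihood method, and the default of this edgeR release, the older method, was used. This was settled after the counts of both methods had been seen: 549, 1974 and 6012 features for A. mexicanum, A. andersoni and A. maculatum with the older method, and 1003, 2093 and 5933 with the newer one. Levels are given as CPM, counts scaled to the TMM-adjusted library size, and fold changes are 24 h over 0 h. Where a group held 0 counts of a feature, the fold is a lower bound against a floor of 3 counts over the group. Where it held 1 to 3 counts, a pooled ratio is given with its 95% counting interval: the counts of the 3 libraries of a time were summed, divided by the sum of their TMM-adjusted sizes, and compared between times, so it differs from the ratio of the mean CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

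The named features are the 2 with the largest rise and the 2 with the largest fall per species among those past the threshold, with a mean of at least 5 CPM and every 24 h library beyond every 0 h library. Replicate numbers are only names in accession order, so libraries were not paired. No pair of libraries held the same values: the chi-square per feature between libraries of a group ranged from 10.6 to 214, where sampling noise alone gives about 1. For measures of whole libraries, 3 libraries against 3 were compared by a two-sided exact permutation test, whose smallest p is 0.1. Differences of the change between species were tested by permuting times within both species over 400 arrangements, and each family of 9 tests was adjusted by Benjamini-Hochberg.

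Library totals were 16827429 to 23412930 expected counts in A. mexicanum, 11416858 to 17206949 in A. andersoni and 8037090 to 14826773 in A. maculatum. The procedure was tested on simulated counts drawn from the means, spread and library sizes of each comparison, with 200 features changed by known folds. Of the features changed 4-fold, 14% were recovered in A. mexicanum, 70% in A. andersoni and 74% in A. maculatum. Of those changed 8-fold, 64%, 98% and 98% were recovered. A feature that misses the threshold, in A. mexicanum above all, is thus not shown to be unchanged. The simulation drew spread from its trend with abundance, made no library stand apart and changed 200 features, while 6012 were called in A. maculatum. It changed only features with a mean of at least 1 CPM, 50 per fold. In A. mexicanum 12862 of the 42641 tested features lay below that mean. The shares recovered are therefore not the sensitivity of the real tests.

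The alternatives were DESeq2 size factors, no filter on low counts, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), features added up per component, an adjusted p of 0.01, an absolute log2 fold change of at least 1, and leaving out each library. Alternatives chosen after seeing the data were library totals without TMM, upper quartile normalization, the newer quasi-likelihood method, the most abundant feature left out, and libraries thinned to 4469810 counts outside that feature. Permutation tests and plots used NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.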

Results

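The series title states that the study sought expression changes after limb amputation that are shared by 3 species of Ambystoma. Tissue at the cut was compared between 0 h and 24 h within each species. The table of A. mexicanum listed 898057 features, that of A. andersoni 889287 and that of A. maculatum 474849, of which 237314, 244050 and 119951 were at 0 in all 6 libraries of the species. The features tested numbered 42641, 34397 and 27360. They held between 96.39% and 99.07% of the counts of each library. Library totals ranged from 16827429 to 23412930 expected counts in A. mexicanum, from 11416858 to 17206949 in A. andersoni and from 8037090 to 14826773 in A. maculatum.

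In A. mexicanum, 517 features rose and 32 fell between 0 h and 24 h, 1.29% of those tested. The median log2 fold change was 3.41 among the features that rose and -2.59 among those that fell. With features at 3 counts or fewer in a group set to the bound of that floor, the medians were 3.42 and -2.59 (in A. andersoni 2.17 and -2.09, in A. maculatum 1.67 and -2.51). The features that rose held 0.405% ± 0.0136 (SD, n = 3) of the counts outside the most abundant feature at 0 h and 2.68% ± 0.291 (SD, n = 3) at 24 h. Those that fell held 0.0758% ± 0.00742 (SD, n = 3) and 0.0138% ± 0.00304 (SD, n = 3). Among rises, 38 features held at least as much of the 24 h share as all the others together. Among falls, 4 features did so for the 0 h share. These shares, like those given below for the other species, describe features selected by the same test.

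The 2 features with the largest rises in A. mexicanum had 0 counts in every 0 h library. Ax_TR94566_c0_g1 reached 14.8 ± 7.99 CPM (SD, n = 3) at 24 h, at least 306-fold higher, with an edgeR adjusted p of 0.033. Ax_TR496356_c10_g3 reached 12.4 ± 3.83 CPM (SD, n = 3), at least 256-fold higher, with an edgeR adjusted p of 0.024. Ax_TR453141_c0_g1 fell from 33.8 ± 5.64 to 3.87 ± 1.28 CPM (SD, n = 3), a log2 fold change of -3.13 (SE 0.35, edgeR adjusted p = 0.027). Ax_TR480527_c7_g1 fell from 107 ± 17.8 to 12.5 ± 6.99 CPM (SD, n = 3), a log2 fold change of -3.09 (SE 0.47, edgeR adjusted p = 0.04).

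These counts for A. mexicanum depended on single libraries. The third 0 h library correlated with the first and second 0 h libraries at r = 0.782 and 0.72 across features, while those 2 correlated with each other at 0.966. Without the third 0 h library 4193 features passed, 3327 higher and 866 lower at 24 h, and they included all 549 of the calls made with it. Their median log2 fold change was 2.86 among rises and -1.8 among falls. Without any 1 of the other 5 libraries edgeR called 0 features, although 4396 to 6675 had an unadjusted p under 0.05 and the DESeq2 test called 1087 to 2729. The 4 named features lost their calls in those 5 fits and kept the sign of their change. With all 6 libraries the DESeq2 test called 3600 features, of which 73.7% rose, and with no filter on low counts edgeR called 3263, of which 72.6% rose, against 94.2% of the 549.

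**Figure D1:**
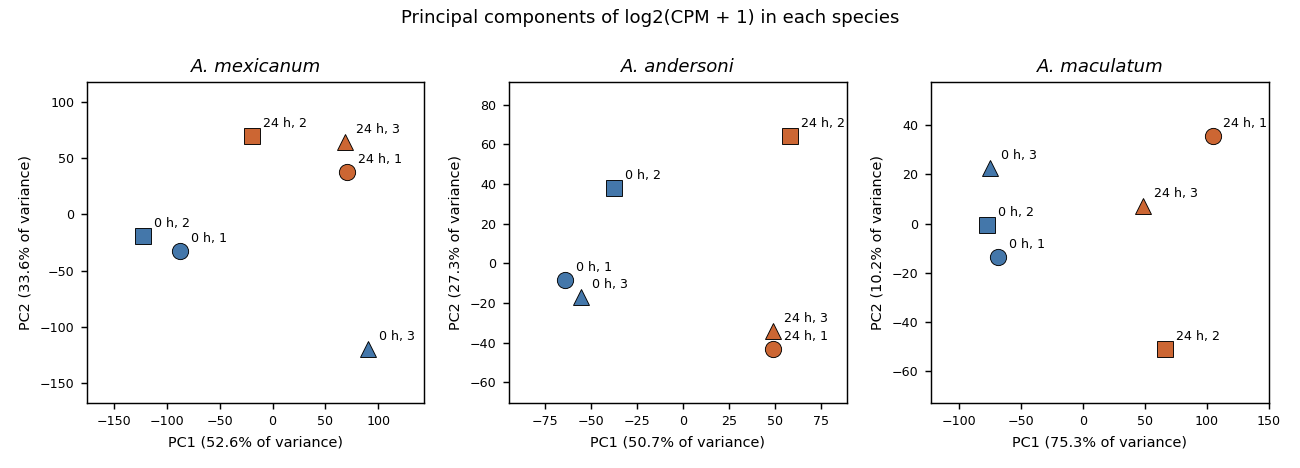
Principal components of log2(CPM + 1) in each species, 1 point per library, with the component scores on both axes; blue points are 0 h and orange points 24 h, and the marker shape and label give the replicate. In A. mexicanum the third 0 h library lies at 90.65 on the first component, near the first (70.76) and the third (68.63) 24 h library while the second lies at -19.75, and at -119.91 on the second, away from all other libraries.

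In A. andersoni, 1299 features rose and 675 fell, 5.74% of those tested. The median log2 fold change was 2.17 among rises and -2.09 among falls, and 1229 rises and 637 falls had an absolute log2 fold change of at least 1. The share of counts outside the most abundant feature went from 2.38% ± 0.303 to 7.93% ± 0.667 (SD, n = 3) for features that rose and from 1.57% ± 0.185 to 0.579% ± 0.0657 (SD, n = 3) for those that fell. Among rises, 14 features held at least as much of the 24 h share as all the others together. Among falls, 38 features did so for the 0 h share.

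And_TR108134_c0_g1 rose from 0.0236 ± 0.0408 to 18 ± 4.11 CPM (SD, n = 3), with 1 count at 0 h in all and a pooled ratio of summed counts of 790 (95% counting interval 141 to 31300, edgeR adjusted p = 0.00087). And_TR444609_c2_g1 rose from 0.0488 ± 0.0845 to 18.3 ± 0.841 CPM (SD, n = 3), a pooled ratio of summed counts of 275 (93.6 to 1340, edgeR adjusted p = 0.00087). Its 3 counts at 0 h all came from the second 0 h library. And_TR539382_c0_g1 fell from 14.4 ± 2.64 to 0.0311 ± 0.0538 CPM (SD, n = 3), a pooled ratio of summed counts, 0 h over 24 h, of 551 (98.6 to 21800, edgeR adjusted p = 0.00087). And_TR47630_c0_g1 fell from 34.0 ± 10.5 to 0.0933 ± 0.162 CPM (SD, n = 3), a pooled ratio of summed counts, 0 h over 24 h, of 412 (141 to 2000, edgeR adjusted p = 0.0013). Its 3 counts at 24 h all came from the third 24 h library.

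Leaving out 1 library gave 534 to 2594 calls in A. andersoni. The median log2 fold change of these calls ranged from 1.99 to 3.12 among rises and from -4.35 to -1.8 among falls. The count moved by over 1.5 times without the first 0 h library (766), the second (1273) or the third (804), and without the first 24 h library (667) or the third (534). No call turned its direction. The share of calls that rose was 65.8%, and was 50.4% of 4165 calls with no filter on low counts and 78.6% of 772 calls among features with a mean of at least 5 CPM.

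In A. maculatum, 2791 features rose and 3221 fell, 22% of those tested. The median log2 fold change was 1.67 among rises and -2.52 among falls. A log2 fold change of at least 3 in size was reached by 492 rises and 1216 falls. The features that fell held 31.5% ± 0.964 (SD, n = 3) of the counts outside the most abundant feature at 0 h and 4.28% ± 1.98 (SD, n = 3) at 24 h. The features that rose held 8.43% ± 0.374 and 24.1% ± 1.16 (SD, n = 3). Few features made up much of these shares. Among falls, 18 features held at least as much of the 0 h share as all the others together. Among rises, 40 features did so for the 24 h share. Of the 53 tested features with a mean of at least 1000 CPM, 9 rose and 17 fell.

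Mac_TR54362_c2_g1 had 0 counts at 0 h and 10.7 ± 4.44 CPM (SD, n = 3) at 24 h, at least 196-fold higher (edgeR adjusted p = 0.00017). Mac_TR45282_c0_g1 rose from 0.0168 ± 0.029 to 23.1 ± 18.1 CPM (SD, n = 3), with 1 count at 0 h in all and a pooled ratio of summed counts of 1100 (95% counting interval 197 to 43700, edgeR adjusted p = 0.00016). Mac_TR48016_c0_g1 had 10.9 ± 3.98 CPM (SD, n = 3) at 0 h and 0 counts at 24 h, at least 97.3-fold lower (edgeR adjusted p = 0.00028). Mac_TR100088_c0_g4 had 10.3 ± 2.45 CPM (SD, n = 3) at 0 h and 0 counts at 24 h, at least 92.0-fold lower (edgeR adjusted p = 0.00015).

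The division of the A. maculatum calls into rises and falls was alike under scalings that centre the fold changes of all features. The median log2 fold change of all tested features was -0.012 with TMM, -0.022 with DESeq2 size factors and -0.016 with upper quartile normalization. Their agreement is thus not independent support for an even division. With TMM 46.4% of 6012 calls rose, with DESeq2 size factors 45.7% of 5997 and with upper quartile normalization 46.4% of 5942. With library totals alone 10.5% of 7163 rose, 752 against 6411, while the median log2 fold change of all tested features moved from -0.012 to -0.856. Without the second 0 h library 3429 features passed, with a median log2 fold change of 2.21 among rises and -3.25 among falls.

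**Figure D2:**
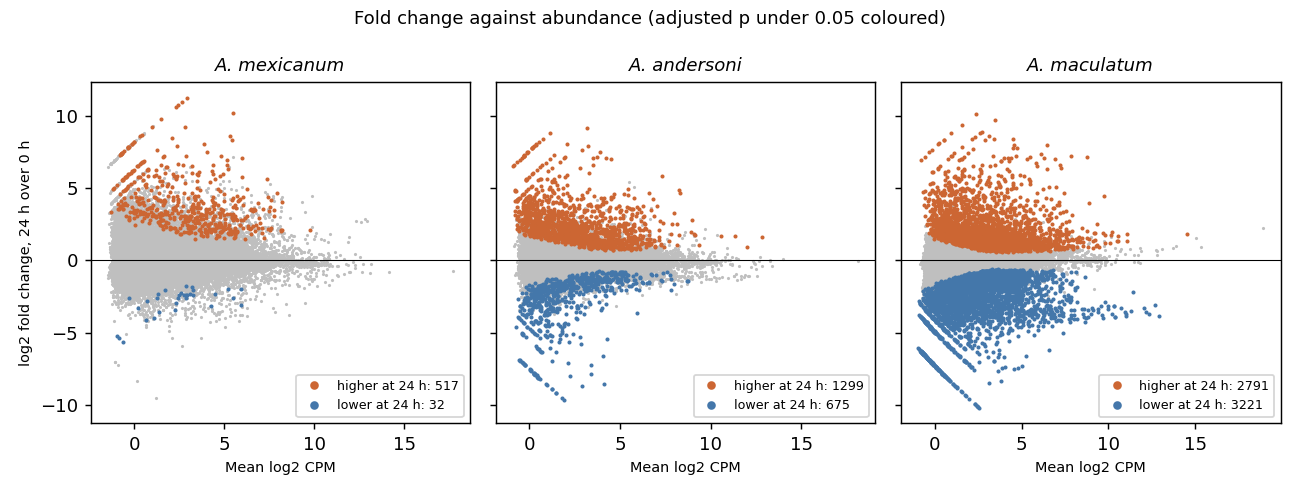
Log2 fold change (24 h over 0 h) against mean log2 CPM for every tested feature of each species; features past the adjusted p threshold of 0.05 are orange where higher at 24 h and blue where lower, and the others are grey. The orange and blue counts are 517 and 32 in A. mexicanum, 1299 and 675 in A. andersoni, and 2791 and 3221 in A. maculatum with TMM; with library totals alone the last pair is 752 and 6411.

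**Figure D3:**
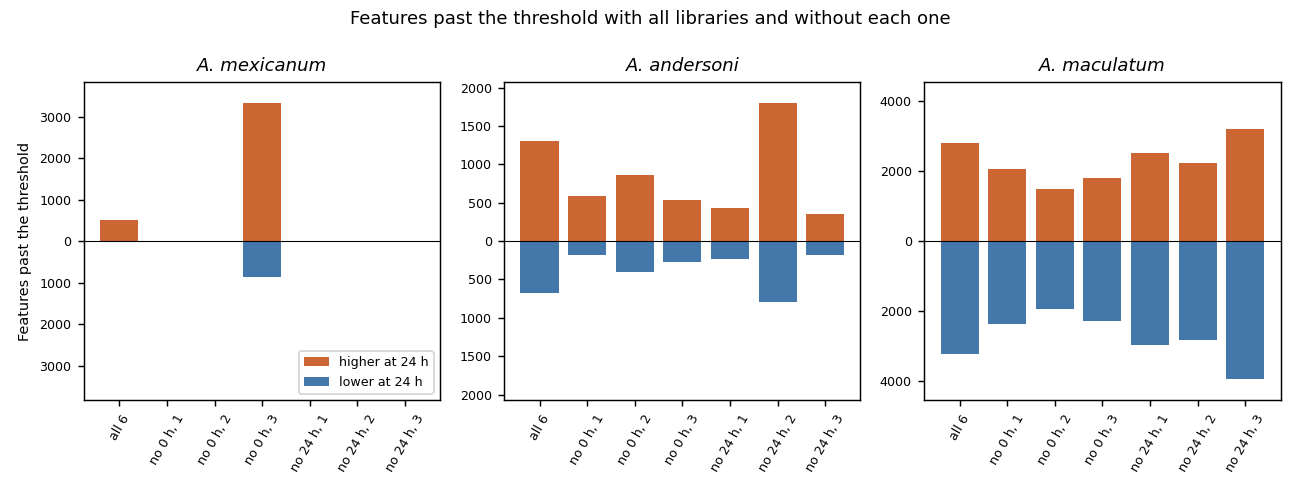
Features past the threshold with all 6 libraries of a species and without each library in turn; bars above the 0 line are features higher at 24 h, bars below it features lower at 24 h, and the vertical scale differs between species. In A. mexicanum the count is 549 with all libraries, 4193 without the third 0 h library and 0 without any 1 of the others.

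The number of calls in 1 species was not compared with that in another by a test. The spread between libraries differed, with a common biological coefficient of variation of 55.9% in A. mexicanum, 32.8% in A. andersoni and 31.5% in A. maculatum. Without the third 0 h library the coefficient of A. mexicanum was 38.2%. Without any 1 of its other libraries it was 54.7% to 60.9%. Features whose 24 h libraries all lay beyond all 0 h libraries, in either direction, made up 25.9% of tested features in A. mexicanum, 28.8% in A. andersoni and 40.1% in A. maculatum, where chance gives 10%. In A. mexicanum 14.7% were higher and 11.2% lower at 24 h, in A. andersoni 13.9% and 14.9%, and in A. maculatum 17.5% and 22.6%.

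The most abundant feature of each table took a large share of the counts. In A. maculatum it held 23.11% ± 2.14 (SD, n = 3) at 0 h and 53.56% ± 10.1 (SD, n = 3) at 24 h, and every 24 h library lay above every 0 h library (two-sided exact permutation p = 0.1, the smallest 3 against 3 can give; Benjamini-Hochberg p = 0.3 over 9 tests). In A. mexicanum it held 24.49% ± 5.84 and 16.16% ± 1.3 (SD, n = 3), and every 24 h library lay below every 0 h library (exact permutation p = 0.1, adjusted p = 0.3). The change was -8.33 percentage points, and -4.98 without the third 0 h library. In A. andersoni the times overlapped, at 25.57% ± 12.3 and 26.82% ± 6.07 (SD, n = 3; exact permutation p = 1.0). The edgeR test did not call the feature in any species, with adjusted p of 0.38 in A. mexicanum, 0.959 in A. andersoni and 0.0731 in A. maculatum.

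**Figure D4:**
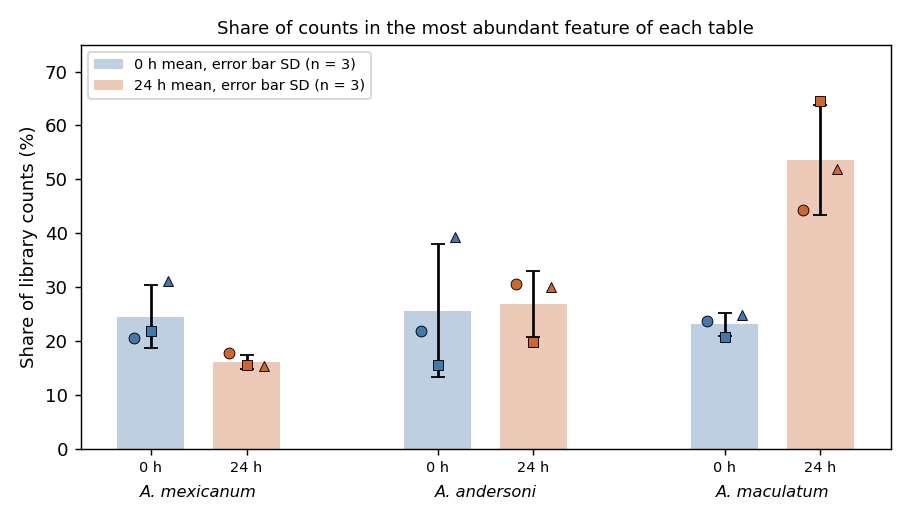
Share of library counts, in percent, held by the most abundant feature of each species' table; bars are means of 3 libraries, error bars the SD, and points single libraries. The A. maculatum libraries lie between 44.38% and 64.45% at 24 h and between 20.73% and 24.86% at 0 h.

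Thinned to equal counts, the libraries of A. andersoni held 141600 ± 9840 features above 0 (SD, n = 3) at 0 h and 167500 ± 11000 (SD, n = 3) at 24 h, with no overlap (exact permutation p = 0.1, Benjamini-Hochberg p = 0.3). In A. mexicanum the numbers were 123600 ± 14500 and 136100 ± 12700 (SD, n = 3; exact permutation p = 0.4). In A. maculatum they were 109500 ± 12300 and 96800 ± 38900 (SD, n = 3; exact permutation p = 0.6).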

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

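Of the tests below, those of a swap and of a tissue mix were chosen after related results had been seen, as were the settings without TMM, with upper quartile normalization, without the most abundant feature and with thinned libraries. For these 2 explanations a first test was replaced after its result or related results were known, and both versions are given. Quartiles, which show the spread among features and not the error of a median, were also brought in afterwards. They leave the wrong label and the tissue mix open, which the medians alone would count against by the rules set. Also chosen afterwards were the intervals of the ratios of falls to rises and the test of the least abundant features. So were the rules that scalings which hardly lower the median fold change, and a setting that keeps nearly all calls, test nothing.

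The share of counts in the most abundant feature changed differently in 2 species. It was 30.5 percentage points higher at 24 h in A. maculatum and changed by -8.33 points in A. mexicanum, a difference of 38.8 points (permutation of times within both species, p = 0.005, the smallest 400 arrangements give; Benjamini-Hochberg p = 0.045 over 9 tests). Without the third 0 h library of A. mexicanum its change was -4.98 points and the difference 35.4 points (permutation p = 0.005). Without any 1 of its 24 h libraries the permutation p was 0.01 and the Benjamini-Hochberg p 0.09. This comparison was not in the plan, and the permutation assumes no effect of time in either species. The feature has no gene name, and no biological explanation was tested.

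In A. maculatum this feature took more counts at 24 h while the calls divided almost evenly, 46.4% of them rises. With no filter on low counts the division was less even, with 37.2% rises (2223 against 3759 falls). Counts taken by the feature were weighed as a source of the 46.4% by leaving it out. The share moved by 0.9 percentage points, under the 10 set for it, and 5925 of the 6012 calls stayed in place. By the rule set this counted against the explanation. But with TMM a setting that keeps nearly all calls in place cannot test it, so the explanation stays open. With library totals alone, a larger share for this feature leaves smaller shares for all others. Counts taken by it may thus contribute there, and the extent was not tested. Fewer counts for other features at 24 h are argued against as the source of the division among features still tested at equal counts. At equal counts outside the most abundant feature the ratio of falls to rises moved by a factor of 1.06, under the 1.5 set for it. The 95% interval of 0.984 to 1.14 takes features as independent and the sets of calls as separate, although 4839 calls were shared. At equal counts 2451 features rose and 2675 fell. The filter was applied again to the thinned counts, so the ratios compared cover different sets of features. Among the 6840 least abundant of the 27360 tested features, against 4961 of 19845 at equal counts, the factor was 1.36. Its interval, made the same way, was 1.09 to 1.69, so for features with few counts this explanation stays open. Rises and falls numbered 73 and 542 below a mean of 1 CPM, 1585 and 1783 from 1 to 10, 997 and 770 from 10 to 100, 127 and 109 from 100 to 1000, and 9 and 17 from 1000 CPM up. The share of rises was 45.7% with DESeq2 size factors and 46.4% with upper quartile normalization, which centre the fold changes as TMM does. With library totals alone it was 10.5%. A true fall of most features at 24 h was not tested.

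In A. mexicanum the third 0 h library stands apart from the other 0 h libraries, and 4 explanations were tested. Low complexity is argued against: at equal counts the library held 138606 features above 0, more than 4 of the other 5 libraries of the species (109604 to 150238). A 24 h library under a 0 h label stays open. The library's position was scaled from the other 0 h libraries (0) to the 24 h libraries (1). Its median was 0.33 (quartiles 0 to 0.72) on features called as rises without it and 0.66 (quartiles 0.09 to 1.21) on falls. In the other species, 24 h libraries had medians of 0.65 to 1.18. By the rule set for it, a median nearer the 0 h libraries on rises or on falls counted against this explanation. The rises met that rule and the falls did not, and the quartiles show only the spread among features. The third 0 h library correlated with the 24 h libraries at r = 0.852, 0.756 and 0.82, and with the other 0 h libraries at 0.782 and 0.72. Among the 24 h libraries r was 0.909 to 0.961. A swap with a 24 h library stays open because its tests conflict. Exchange with the second 24 h library gave 104 features at 0 on 1 side and above 0 in all libraries of the other. By the labels the number was 77. Yet the first test left each 24 h library closer to the other 24 h libraries by an r of at least 0.026. The exchanged split held 46.1% of the variance between its sides against 37.5% by the labels, but called 0 features against 549. Another mix of tissues may contribute and stays open. Features at least 8-fold lower in the third 0 h library held at least 7.87% of counts in the other 0 h libraries. In the second 24 h library they were higher than in the other 2 by a median log2 of 1.41 (quartiles 0.85 to 2.25). Their share of counts was 8.27% there, against 4.34% in the first 24 h library and 8.49% in the third. Features at least 8-fold higher in the third 0 h library differed by a median of -0.79 (quartiles -1.24 to -0.24). This is short of the bound of 1 set for it, and without gene names no tissue can be named.

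Rises outnumbered falls among the calls of A. mexicanum and A. andersoni. The scaling of the libraries stays open: the lowest share of rises over both species and 4 other scalings was 66.6%, but these scalings lowered the median log2 fold change of all features only from -0.09 to -0.14 in A. mexicanum and not at all in A. andersoni, too little to test it. Easier calls of low-abundance features are argued against, since at a mean of at least 5 CPM the lower share was 71.3%. The excess in A. mexicanum is smaller with other settings, 79.3% without the third 0 h library and 73.7% with DESeq2, and in A. andersoni it all but vanished with no filter on low counts, at 2101 rises against 2064 falls (50.4%). Features whose libraries did not overlap were not more often higher in A. andersoni, at 13.9% against 14.9%. Time after amputation remains among the open explanations, as a hypothesis from the same data.

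Whether chance can account for the number of calls cannot be decided from 10 splits of 6 libraries, where the share of splits is never under 0.1. The split by labels called 549 features in A. mexicanum, 1974 in A. andersoni and 6012 in A. maculatum, and the highest of the other splits called 0 in each, so 1 split of 10 reached the real count.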

How the results depend on the processing

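Library totals without TMM, upper quartile normalization, the newer quasi-likelihood method, the most abundant feature left out and thinned libraries were chosen after seeing the data. In A. mexicanum, against 549 calls, no filter on low counts gave 3263, the DESeq2 test 3600, an adjusted p of 0.01 gave 0 (7414 features had an unadjusted edgeR p under 0.05), library totals alone 962 and the newer quasi-likelihood method 1003. Leaving out 1 library gave 0 to 4193, the highest without the third 0 h library. In A. andersoni, against 1974, no filter gave 4165, a mean of at least 5 CPM 772, DESeq2 3341, an adjusted p of 0.01 gave 321 and library totals alone 1238. Leaving out 1 library gave 534 to 2594. In A. maculatum, against 6012, a mean of at least 5 CPM gave 3428 among fewer tested features and an adjusted p of 0.01 gave 3274. Leaving out 1 library gave 3429 to 7139. Library totals alone moved the division there to 752 rises and 6411 falls from 2791 and 3221. Where a setting did not itself remove features or libraries or tighten the threshold, the cause was not tested. The other settings stayed within 1.5 times, 8 in A. mexicanum, 9 in A. andersoni and 16 in A. maculatum. Where calls could be matched by feature, 0 shared calls had the opposite direction. The 4 named features of A. mexicanum lost their calls in 25 of their 68 fits and kept their direction; the 4 of each other species kept call and direction in all 68. Thinned libraries gave 395, 1387 and 5126 calls. In simulated counts 0% of 2-fold changes were recovered in A. mexicanum, 10% in A. andersoni and 16% in A. maculatum, which does not tell depth from spread as the limit. The planned tests per gene symbol, of gene lists, of overlap, of interaction and of correlation between species, and all their alternatives, were not run, since no feature was matched to a gene. No paired analysis was possible because the replicate numbers only follow accession order.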

Other observations

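A component in the feature IDs groups features that were assembled together. Among components with 2 or more calls, all calls had the same direction in 153 of 161 in A. andersoni and in 626 of 649 in A. maculatum. In 1000 shuffles of the directions the highest numbers were 101 and 329 (one-sided permutation p = 0.001 in both, the smallest 1000 shuffles can give). A candidate explanation is that pieces of the same gene were split over several features, so that calls count some genes more than once. Features of related genes in 1 component would give the same pattern and were not told from it. In A. mexicanum all 43 of 43 components had 1 direction, against a median of 38 in the shuffles (highest 43, one-sided permutation p = 0.007). The rule set, a number above that of every shuffle, could not be met there. Components holding a feature that rose numbered 474 in A. mexicanum and those holding one that fell 31, against 1154 and 632 in A. andersoni, and 2409 and 2791 in A. maculatum. With counts added up per component before the edgeR test, 727 components rose and 90 fell in A. mexicanum, 1464 and 922 in A. andersoni, and 2556 and 2889 in A. maculatum.

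Features with 0 counts in every library of 1 time and counts in all 3 of the other were unevenly spread. In A. mexicanum 72 tested features appeared only at 24 h and 5 only at 0 h, in A. andersoni 23 and 36, and in A. maculatum 11 and 147. Of these, 25 of the 72 and 0 of the 5 passed the edgeR threshold in A. mexicanum, and all of them did in the other 2 species. The A. maculatum libraries had fewer counts outside the most abundant feature at 24 h, 4469810 to 7078306 against 9303743 to 11752207. Whether its features at 0 at 24 h were absent or below detection was not tested.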
